A study of Arabidopsis thaliana with 26 samples.

How the data were processed

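Small RNA of 10 to 60 nt was cut from gels and made into libraries with a NEXTflex kit and sequenced on a HiSeq2000, per the labels' protocols. Tagged AGO1 was recovered on IgG Sepharose beads. The deposited files hold raw read counts per distinct sequence for reads of 13 to 40 nt, with no header. The submitters' processing notes name the genome build TAIR10, and the adapter trimming and filtering steps are not given in the sources used here. Reads outside 13 to 40 nt were not analysed here. Groups and replicate numbers came from the sample titles, since file names carry other replicate numbers.

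Reads were assigned to features by exact sequence match to the RefSeq genome and annotation TAIR10.1, which was not compared with TAIR10. Listed miRNAs were read as reads of 19 to 25 nt that begin with the first 18 nt of the mature sequence. Of 77 list entries, 74 equal an annotated mature sequence. Other reads of 20 to 24 nt in the 326 annotated hairpins and reads of 18 to 25 nt in 8 TAS genes were counted per gene. Reads of 684 annotated tRNA genes were grouped by anticodon, genome compartment, part of the tRNA (5′ end, 3′ end with or without CCA, internal) and length (13 to 17, 18 to 25 or 26 to 40 nt). Internal reads may lie a few nt from an end. Plastid tRNAs are named by amino acid because the annotation gives no anticodon, and 18 nuclear copies of organelle tRNAs were left out. The 82 snRNA and 287 snoRNA genes and the rRNAs were counted per gene. An annotated 5S gene that is a 5.8S copy was counted as 5.8S, and 3800 nt after 5.8S on chromosome 3 (14199917 to 14203716) stood in for 25S. Reads shared by several genes formed a feature of their own, so copies of 1 family are not separated. Features with at least 20 reads over all libraries were kept. They held 39.3% to 54.4% of the reads of total RNA libraries and 20.6% to 82.7% of those of the other libraries.

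Features were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), by its quasi-likelihood test on the counts, with total deposited reads as library size, filterByExpr, and Benjamini-Hochberg adjustment at 0.05 over all features tested. WT and dcl1 formed a fit of 8 libraries and 998 features (common biological coefficient of variation 0.294). Input, AGO1 IP and mock IP formed a fit of 18 libraries and 1363 features (0.953). Comparisons of dcl1 with WT and of the IP with input or mock averaged both times. Lists were tested with camera at a preset correlation of 0.01, with a prior count of 2 and at least 3 members, and again with an estimated correlation. The lists, the tests and the naming rule were fixed before the data were examined. They were conserved, lineage-specific, passenger-strand, nutrient-responsive, hormone-related, phased-siRNA-trigger, pathway-targeting and A-starting miRNAs, TAS genes, 6 sets of tRNA fragments, snoRNA, snRNA, rRNA and plastid rRNA. A list of DCL1-independent miRNAs (miR822, miR839 and miR869) had under 3 members past the filter and was not tested. Shares of 21 read classes (17 for the IP) were tested by a two-sided exact permutation test of mean log2 percent within time points, or within genotypes for wounding, with Benjamini-Hochberg adjustment over the classes.

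The features named were, per comparison, up to 5 of the largest rises and 5 of the largest falls in each of 3 classes (miRNA and tasiRNA, tRNA-derived, other). They had to pass the adjusted threshold, to have all libraries of 1 arm beyond the mean of the other and to reach 10 RPM in an arm. Another 12 features were always given, passing or not. For features with 3 or fewer reads in an arm read counts are given, and a fitted value of theirs is no bound. For 0 reads the level that 3 counts would have is given as the limit.

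Alternatives planned in advance were DESeq2 1.42.0 with its own size factors, TMM factors, no low-count filter, library size over 18 to 28 nt reads, exact mature miRNA counts, a replicate block, each library left out in turn, an estimated correlation, and for shares a genome-matched denominator or an 18 to 28 nt window. Further ones were chosen after seeing the data. These were library size without tRNA and rRNA reads, leaving out AGO1 IP 3 h replicate 3 and mock IP 3 h replicate 1, the 4 libraries with the fewest genome matches or the 6 with under 2000000 reads, fits of input, of IP or of both alone, and input libraries as a further stratum. Genome matches used bwa 0.7.19, and counting used Python 3.11.15 with numpy 2.4.6 and figures matplotlib 3.10.9.

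The procedures were tested on simulated counts with 200 changed features, 100 per fold size. For dcl1 against WT, 53 of 100 changes of 2-fold and 95 of 100 of 4-fold were recovered with 4 of 798 unchanged features called, and for wounding in WT 26 and 76 with 3 called. For AGO1 IP against input 0 and 13 were recovered, against mock 2 and 10, and for wounding in the input or the IP 0 and 0, so these fits miss most changes of that size. The list test found a raised list except for wounding in the IP. The share test called 7 of 200 unchanged simulations and 199 of 200 shifted by log2 3. In total RNA alone the smallest possible p is 0.0556, so no class can pass there. No replicate pair agreed within sampling noise (chi-square per degree of freedom 29.7 to 3252.9), so each library counted once.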

Results

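Small RNAs were sequenced from leaves of 4-week-old Arabidopsis thaliana plants (accession Col-0) that were unwounded (0 h) or harvested 3 h after wounding. The 26 libraries fell into 10 groups. Total small RNA of wild type (WT) and of a dcl1 mutant had 2 libraries per time point. DCL1 is the Dicer-like enzyme that makes most plant miRNAs. Sample titles call the allele dcl1-27, the series text dcl1-7. Plants carrying tagged AGO1, the main miRNA-binding Argonaute of plants, in the ago1-27 background gave input RNA, AGO1 immunoprecipitate (IP) and mock IP, with 3 libraries each per time point. Titles place the mock in the tagged plants, whereas the series text describes an IP from wild type. The series text calls replicates biological.

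By sample type, total RNA libraries held 2537868 to 3952631 reads, input libraries 605380 to 19068203, AGO1 IP libraries 125299 to 19235262 and mock IP libraries 333025 to 12649771. The 6 libraries numbered replicate 3 all held under 2000000 reads. The lowest shares of 18 to 40 nt reads that matched the genome were those of mock IP 3 h replicate 1 (21.26%), mock IP 0 h replicates 1 (38.38%) and 3 (46.3%) and AGO1 IP 3 h replicate 3 (54.98%). Levels are in RPM, over all deposited reads of a library. Changes are log2 fold changes ± SE, and the first level of a pair belongs to the first-named arm. In each feature named for a large change, all libraries of 1 arm lay beyond the mean of the other arm, except for the interactions, to which that criterion was not applied. Limits for 0 reads cover counting error only.

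In unwounded WT leaves, miRNAs of the fixed list took 15.47% ± 4.49 of all reads (SD, n = 2), tRNA-derived reads 7.451% ± 0.400 and rRNA-derived reads 12.73% ± 3.60. After wounding, the WT shares were 8.697% ± 1.42 for miRNAs, 27.47% ± 4.46 for tRNA-derived reads and 10.79% ± 0.972 for rRNA-derived reads. In dcl1 the miRNA share was 3.056% ± 0.298 without wounding and 1.951% ± 0.347 after it, and the tRNA-derived share was 15.65% ± 0.112 and 29.50% ± 3.03. Input RNA held 10.97% ± 1.40 tRNA-derived reads at 0 h and 39.66% ± 1.95 at 3 h (n = 3). The AGO1 IP held 69.77% ± 0.463 miRNA reads at 0 h and 56.52% ± 21.7 at 3 h, with tRNA-derived shares of 0.1453% ± 0.0909 and 0.2104% ± 0.0734. Mock IP libraries held 10.24% ± 6.70 and 25.59% ± 20.6 miRNA reads.

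**Figure D1:**
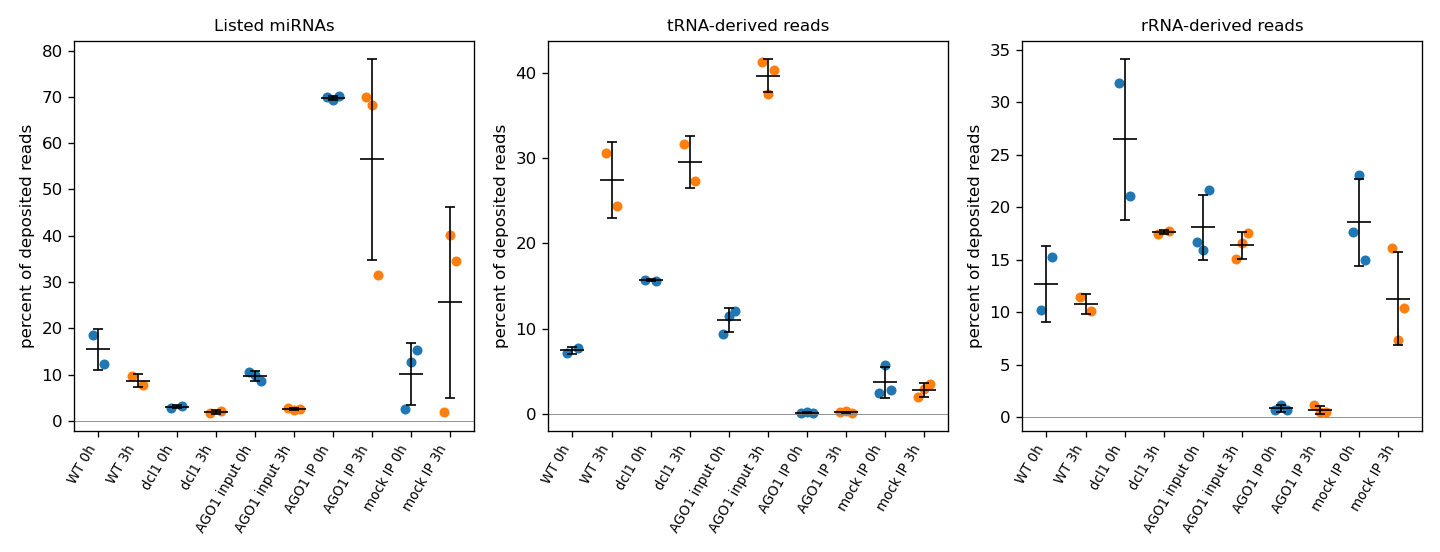
Percent of deposited reads from listed miRNAs, tRNAs and rRNAs in each library (points, blue 0 h, orange 3 h) with the group mean and SD (bars). The tRNA-derived share lies at 7.451% in unwounded WT and 27.47% in wounded WT, and at 0.1453% in the unwounded AGO1 IP.

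**Figure D2:**
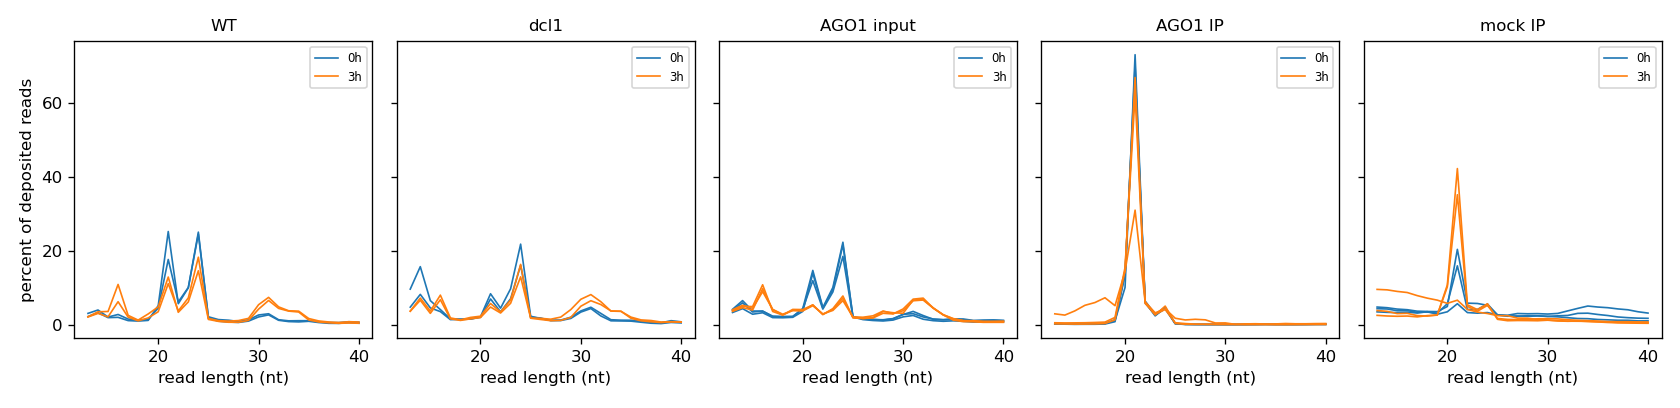
Percent of deposited reads at each read length from 13 to 40 nt, with 1 line per library (blue 0 h, orange 3 h) and 1 panel per sample type. In the first unwounded WT library 25.25% and in the first unwounded AGO1 IP library 73.12% of reads were 21 nt long.

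To find which leaf small RNAs depend on DCL1, dcl1 was compared with WT, both times averaged (n = 4 libraries per genotype). Most miRNAs and all tasiRNAs of the TAS genes were lower in the mutant. miR173, the trigger of TAS1 and TAS2 tasiRNAs, fell 577-fold (log2 -9.17 ± 0.48, 1.22 against 699 RPM, edgeR adjusted p = 2.30e-12), and TAS2 tasiRNAs fell 519-fold (-9.02 ± 0.41, 11.9 against 6500.0 RPM, adjusted p = 4.43e-13). miR158a fell 125-fold (log2 -6.97 ± 0.32, 149 against 18918 RPM, edgeR adjusted p = 4.43e-13). Of 124 internal fragments of nuclear tRNAs 45 were higher and 3 lower. Those of tRNA-Met-CAT of 26 to 40 nt rose 8.37-fold (log2 3.06 ± 0.31, 361 against 40.3 RPM, edgeR adjusted p = 4.85e-08). They were led by a sequence from tRNA position 5 (59.4%). Small RNA libraries do not read the DCL1 mRNA, so the miRNA fall is the available check of the mutant label.

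Of 998 features tested, 127 were higher and 159 lower. Among 58 listed miRNAs, 4 were higher and 45 lower (median log2 -2.54). The 9 TAS features were all lower (median log2 -7.86), 92 of 172 other hairpin features were lower and 17 higher, and of 609 tRNA-derived features 96 were higher and 8 lower. miR159, which targets MYB genes, fell 3.25-fold (log2 -1.70 ± 0.27, 11662 against 37628 RPM, edgeR adjusted p = 2.25e-05). miR166, which targets class III HD-ZIP genes, fell 5.27-fold (log2 -2.40 ± 0.29, 309 against 1663 RPM, edgeR adjusted p = 6.86e-07), and miR163 fell 34.3-fold (-5.10 ± 0.30, 80.1 against 2637 RPM, adjusted p = 1.17e-11). miR398, which targets copper/zinc superoxide dismutases, fell 211-fold (log2 -7.72 ± 0.51, 0.418 against 86.2 RPM, edgeR adjusted p = 5.72e-11). miR822, a miRNA known to be made by DCL4, fell 2.17-fold (log2 -1.12 ± 0.30, edgeR adjusted p = 0.00583), and this call was lost when either of 2 libraries was left out (WT 0 h replicate 1 or dcl1 3 h replicate 1). miR168, which targets AGO1, did not pass (log2 -0.42 ± 0.27, edgeR adjusted p = 0.279). Nor did miR390, the trigger of TAS3 tasiRNAs (log2 -0.27 ± 0.28, edgeR adjusted p = 0.553). tasiRNA reads of TAS1A fell 397-fold, those shared by TAS1A, TAS1B and TAS1C 358-fold and those of TAS1B 327-fold, all with edgeR adjusted p at most 2.74e-12.

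Reads from the MIR8183 hairpin rose most, 233-fold (log2 7.86 ± 0.44, 213 against 1.09 RPM, edgeR adjusted p = 4.32e-12). miR840 rose 17.7-fold (log2 4.15 ± 0.47, 317 against 15.8 RPM, edgeR adjusted p = 3.04e-07), and the passenger strand of miR408 rose 4.8-fold (2.26 ± 0.31, 121 against 26.1 RPM, adjusted p = 4.49e-06). Reads from the MIR781a and MIR171b hairpins rose 4.8-fold (edgeR adjusted p = 4.60e-06) and 4.77-fold (adjusted p = 4.15e-06). Internal fragments of 26 to 40 nt also rose for nuclear tRNA-Asp-GTC (5.93-fold, led from position 4), tRNA-Val-TAC (5.69-fold) and tRNA-Thr-CGT (5.6-fold), as did 18 to 25 nt internal fragments of tRNA-Met-CAT (5.71-fold). Their edgeR adjusted p-values were 9.53e-07, 1.07e-05, 3.03e-05 and 1.06e-06. Lower in dcl1 were 26 to 40 nt 5′ fragments of plastid tRNA-Arg (log2 -2.18 ± 0.32, edgeR adjusted p = 1.27e-05) and of plastid tRNA-Cys (-1.50 ± 0.32, adjusted p = 0.000846). The 26 to 40 nt internal fragments of plastid tRNA-Cys fell 2.37-fold (edgeR adjusted p = 0.0229). The 13 to 17 nt internal fragments of nuclear tRNA-Ser-AGA (log2 -1.01 ± 0.28, edgeR adjusted p = 0.00678) and the 26 to 40 nt 3′ fragments of mitochondrial tRNA-Glu-TTC (-0.87 ± 0.32, adjusted p = 0.0455) were also lower.

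Among the 18 to 25 nt 5′ tRNA fragments fixed in advance, that of nuclear tRNA-Asp-GTC rose (log2 0.94 ± 0.29, edgeR adjusted p = 0.0157). Those of tRNA-Gly-TCC (log2 0.64 ± 0.27, edgeR adjusted p = 0.0849), tRNA-Ala-AGC (0.15 ± 0.27, adjusted p = 0.767) and tRNA-Arg-CCT (-0.06 ± 0.31, adjusted p = 0.936) did not pass. Of the other RNAs, 18S rRNA reads rose 2.4-fold (log2 1.26 ± 0.25, 122428 against 49678 RPM, edgeR adjusted p = 0.000311), and reads shared by 25S and plastid 23S rRNA rose (1.10 ± 0.32, adjusted p = 0.0103). Among spliceosomal RNAs, reads shared by U2.10, U2.2 and U2.3 (log2 1.23 ± 0.38, edgeR adjusted p = 0.0160), U2.7 (1.22 ± 0.38, adjusted p = 0.0193) and U12 (0.94 ± 0.31, adjusted p = 0.0290) were higher. The snoRNAs AT3G01316 (log2 -1.34 ± 0.34, edgeR adjusted p = 0.00416), AT4G04465 (-0.95 ± 0.31, adjusted p = 0.0262) and AT3G03175 (-0.90 ± 0.29, adjusted p = 0.0247), a class that mostly guides rRNA modification, were lower.

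By list, the 29 miRNAs conserved among plants had 24 lower and 1 higher, or 26 adjusted over the list alone (median -2.69, camera adjusted p = 6.90e-13, adjusted p = 0.111 with estimated correlation). Of 22 lineage-specific miRNAs 16 were lower and 1 higher, with 20 adjusted over the list alone (median -3.29, camera adjusted p = 9.23e-11, adjusted p = 0.140 with estimated correlation). All 6 miRNAs that target jasmonate- or auxin-related genes, such as miR159 and miR319, were lower, with 6 adjusted over the list alone (median -3.87, camera adjusted p = 8.12e-06, adjusted p = 0.0794 with estimated correlation). Of 6 triggers of phased siRNAs 3 were lower (median -0.95, camera adjusted p = 0.00915, adjusted p = 0.254 with estimated correlation), and of the 3 miRNAs that target DCL1, AGO1 and AGO2 mRNAs (miR162, miR168 and miR403) 2 were lower (median -3.69, camera adjusted p = 0.00655, adjusted p = 0.277 with estimated correlation), or 4 and 2 adjusted over the list alone. The 9 TAS features were lower with 9 adjusted over the list alone (median -7.86, camera adjusted p = 4.84e-11, adjusted p = 0.0363 with estimated correlation), the 1 list call that held with an estimated correlation.

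Of the nuclear internal tRNA fragments 52 of 124 passed adjusted over the list alone (median 0.70, camera adjusted p = 8.51e-09, adjusted p = 0.277 with estimated correlation). Of 94 nuclear fragments of 26 to 40 nt 33 were higher and none lower, with 33 adjusted over the list alone (median 0.59, camera adjusted p = 5.22e-09, adjusted p = 0.277 with estimated correlation). Of 165 plastid tRNA features 13 were higher and 3 lower, or 5 adjusted over the list alone (median 0.19, camera adjusted p = 0.0195, adjusted p = 0.277 with estimated correlation). The other lists were not called by camera (adjusted p at least 0.117). Nuclear 5′ fragments of 18 to 25 nt had 8 of 42 higher (median 0.15), nuclear 3′ fragments 0 of 47 past edgeR's threshold (0.01), rRNAs 3 of 16 higher (0.12) and plastid rRNAs 1 of 10 (0.06). Of 6 members each, passenger strands had 2 higher and 4 lower (-1.79), nutrient-responsive miRNAs 1 and 4 (-2.08) and A-starting miRNAs 2 and 2 (0.15, but a mean of -0.24 and a downward test). Mitochondrial tRNA features had 3 higher and 2 lower of 30 (-0.06), snoRNAs 2 and 3 of 108 (-0.10) and snRNAs 5 and 2 of 26 (-0.20), each with an upward test. In this order the 10 lists had 7, 0, 3, 1, 6, 6, 4, 2, 0 and 5 members adjusted over the list alone.

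As a share of all reads, miRNAs were 2.504% in dcl1 and 12.08% in WT, below the WT mean in 4 of 4 libraries (exact permutation p = 0.0556, the smallest possible in this design, adjusted p = 0.130). With TMM factors 77 features were higher and 203 lower, and with library size over 18 to 28 nt reads 251 were higher and 130 lower, or 222 and 135 without tRNA and rRNA reads in it. Leaving out 1 library ended the calls of the mitochondrial tRNA-Glu-TTC, internal plastid tRNA-Cys and nuclear 5′ tRNA-Asp-GTC fragments, the named snRNAs, AT4G04465, AT3G03175 and the 25S/23S reads in at least 1 case each. Without dcl1 0 h replicate 2 miR173 was at log2 -10.22 and TAS1B at -9.05, without dcl1 3 h replicate 1 miR398 was at -8.94 and miR840 at 3.53, and without WT 3 h replicate 2 miR840 was at 4.75.

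Wounded WT leaves were compared with unwounded ones (n = 2 libraries per time point). Of 609 tRNA-derived features 189 rose and 36 fell, and 17 of 58 listed miRNAs fell and none rose. The 18 to 25 nt 5′ fragments of plastid tRNA-Arg rose 98.3-fold (log2 6.62 ± 0.51, 1537 against 15.6 RPM, edgeR adjusted p = 2.01e-08), and those of nuclear tRNA-Arg-CCT rose 8.85-fold (3.15 ± 0.47, 4706 against 532 RPM, adjusted p = 3.77e-05). miR390 fell 2.96-fold (log2 -1.57 ± 0.40, 333 against 985 RPM, edgeR adjusted p = 0.00544), and miR395b, which targets genes of sulfate assimilation, fell 3.75-fold (-1.91 ± 0.41, 34.0 against 128 RPM, adjusted p = 0.00130).

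In total 222 features were higher and 82 lower, 33 snRNA and snoRNA features were higher and none lower, and the listed miRNAs had a median log2 of -0.80. Also strongly higher were plastid tRNA-Pro internal fragments of 26 to 40 nt (56.6-fold, log2 5.82 ± 0.52, edgeR adjusted p = 1.09e-07) and 5′ fragments of 13 to 17 nt (37-fold, 5.21 ± 0.42, 7293 against 197 RPM, adjusted p = 2.07e-08). The 26 to 40 nt 5′ fragments of plastid tRNA-Tyr rose 36.7-fold (log2 5.20 ± 0.57, edgeR adjusted p = 8.52e-07) and those of mitochondrial tRNA-Gln-TTG 30.2-fold (4.92 ± 0.66, adjusted p = 8.95e-06). Fragments from 3′ ends made up the largest falls among tRNA features. These were 18 to 25 nt fragments of tRNA-Leu-CAG (log2 -2.48 ± 0.48, edgeR adjusted p = 0.000559), tRNA-Ser-TGA (-2.09 ± 0.45, adjusted p = 0.00136) and tRNA-Leu-TAG (-1.96 ± 0.44, adjusted p = 0.00177). Others were 13 to 17 nt fragments of tRNA-Leu-TAA (log2 -2.08 ± 0.41, edgeR adjusted p = 0.000594) and plastid initiator tRNA-Met (-2.35 ± 0.52, adjusted p = 0.00165).

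Reads from the MIR843 hairpin outside its mature sequence fell 8.61-fold (log2 -3.11 ± 0.58, edgeR adjusted p = 0.000381), and miR843 fell 6.16-fold (-2.62 ± 0.51, 22.0 against 136 RPM, adjusted p = 0.000559). Reads from the hairpins of MIR157c, a family that targets SPL genes, and MIR164c, a family that targets NAC genes, fell 3.87-fold (log2 -1.95 ± 0.43, edgeR adjusted p = 0.00165) and 3.55-fold (-1.83 ± 0.54, adjusted p = 0.0148). miR166 (log2 -1.08 ± 0.39, edgeR adjusted p = 0.0410) and miR398 (-1.17 ± 0.43, adjusted p = 0.0422) were lower. miR158a (log2 -0.53 ± 0.35, edgeR adjusted p = 0.258), miR159 (-0.51 ± 0.37, adjusted p = 0.301), miR163 (-0.62 ± 0.36, adjusted p = 0.207), miR168 (-0.80 ± 0.38, adjusted p = 0.119) and miR822 (-0.23 ± 0.41, adjusted p = 0.695) did not pass. The 5′ fragments of 18 to 25 nt rose for tRNA-Gly-TCC (log2 1.76 ± 0.39, edgeR adjusted p = 0.00165) and tRNA-Asp-GTC (1.23 ± 0.41, adjusted p = 0.0275), and that of tRNA-Ala-AGC did not pass (-0.90 ± 0.38, adjusted p = 0.0750). Of the spliceosomal RNAs, U1.5 rose 7.82-fold (log2 2.97 ± 0.45, edgeR adjusted p = 3.71e-05), and reads shared by U4.10, U4.2 and U4.5 were also called higher (73 against 1 reads, 11 against 0.165 RPM, adjusted p = 6.59e-06). The snoRNAs AT4G06705 (log2 3.21 ± 0.60, edgeR adjusted p = 0.000370), AT1G06453 (2.70 ± 0.53, adjusted p = 0.000571) and AT3G07725 (2.53 ± 0.52, adjusted p = 0.000938) rose.

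By list, 11 of 29 conserved (median -0.86, camera adjusted p = 2.60e-05), 4 of 22 lineage-specific (median -0.57, adjusted p = 0.00383) and 4 of 6 nutrient-responsive miRNAs (median -1.20, adjusted p = 0.0125) and 14 of 47 nuclear 3′ fragments of 18 to 25 nt (median -0.94, adjusted p = 9.89e-09) fell. Higher were 40 of 124 nuclear internal fragments (median 0.69, camera adjusted p = 7.54e-05), 42 of 94 nuclear fragments of 26 to 40 nt (median 1.28, adjusted p = 5.14e-08), 64 of 165 plastid tRNA features, with 3 lower (median 0.69, adjusted p = 5.69e-06), and 9 of 26 snRNAs (median 0.98, adjusted p = 0.0129). In this order 11, 3, 4, 16, 40, 50, 70 and 9 passed adjusted over the list alone, and with an estimated correlation each adjusted p was 0.307. Nuclear 5′ fragments of 18 to 25 nt moved both ways, 12 higher and 3 lower of 42, or 15 adjusted over the list alone (median -0.10, camera adjusted p = 0.721), with a mean of 0.48 and an upward test against the median.

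Over WT and dcl1 together, the tRNA-derived share was 28.49% after wounding and 11.55% before, a 2.63-fold difference (exact permutation p = 0.0556, the smallest possible, adjusted p = 0.0897), and the miRNA share was 5.324% against 9.264%. The count of changed features was 184 without WT 0 h replicate 1 and 179 without WT 3 h replicate 1, and the calls of miR166, miR398, tRNA-Asp-GTC, MIR164c and miR390 were each lost in at least 1 such fit. With DESeq2's size factors 160 features were higher and 143 lower, with library size over 18 to 28 nt reads 293 and 12 and without tRNA and rRNA reads in it 264 and 21, and the miRNA median stayed below 0 (log2 -1.08, -0.23 and -0.42) with 28, 4 and 6 listed miRNAs lower. Without WT 3 h replicate 1 tRNA-Arg-CCT was at log2 2.14 and MIR164c at -1.24, without WT 3 h replicate 2 MIR164c was at -2.68 and plastid tRNA-Tyr at 4.56, and without WT 0 h replicate 1 miR843 was at -1.73, its hairpin at -1.94 and MIR164c at -1.19. Without WT 0 h replicate 2 that hairpin was at -3.74 and AT1G06453 at 3.45.

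In wounded dcl1 leaves 116 of 609 tRNA-derived features were higher and 65 lower than at 0 h, and 52 of 134 snRNA and snoRNA features higher and none lower (n = 2 libraries per time point). Far fewer falls were called without some single libraries. The 18 to 25 nt 5′ fragments of plastid tRNA-Arg rose 35.4-fold (log2 5.15 ± 0.48, 703 against 19.8 RPM, edgeR adjusted p = 2.90e-07) and the 26 to 40 nt 5′ fragments of plastid initiator tRNA-Met 22.3-fold (4.48 ± 0.41, 1420.3 against 63.7 RPM, adjusted p = 2.90e-07). Reads shared by U1.5 and U1.8 snRNA rose 18.6-fold (log2 4.22 ± 0.79, 21.9 against 1.12 RPM, edgeR adjusted p = 0.000589). miR390 fell 4-fold (log2 -2.0 ± 0.41, 237 against 948 RPM, edgeR adjusted p = 0.00115), and miR172, which targets AP2-like genes, rose 2.15-fold (1.11 ± 0.40, 118 against 54.8 RPM, adjusted p = 0.0480).

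In total 173 features were higher and 83 lower. Of the listed miRNAs 2 were higher and 4 lower (median log2 -0.32). The 26 to 40 nt 5′ fragments of mitochondrial tRNA-Gln-TTG (log2 4.67 ± 0.66, edgeR adjusted p = 3.75e-05) and plastid tRNA-Tyr (4.25 ± 0.56, adjusted p = 2.00e-05) and the 18 to 25 nt 5′ fragments of nuclear tRNA-Arg-TCT (4.12 ± 0.50, adjusted p = 7.77e-06) rose. miR163 was 2.06-fold higher (log2 1.04 ± 0.37, edgeR adjusted p = 0.0441), as were hairpin reads of MIR843 (1.98 ± 0.64, adjusted p = 0.0274) and of the MIR172 family (1.62 ± 0.52, adjusted p = 0.0252). Reads from the MIR169h hairpin (log2 -2.99 ± 0.55, edgeR adjusted p = 0.000483), the MIR169 family hairpins (-2.10 ± 0.46, adjusted p = 0.00222), the MIR390 hairpins (-2.08 ± 0.52, adjusted p = 0.00587) and the MIR164c hairpin (-1.89 ± 0.54, adjusted p = 0.0147) fell. Other rises were in snoRNA AT1G06453 (log2 3.80 ± 0.59, edgeR adjusted p = 9.48e-05), reads shared by U2.10, U2.2 and U2.3 (3.4 ± 0.50, adjusted p = 5.29e-05), U1.5 (2.93 ± 0.47, adjusted p = 0.000126) and U2.6 (2.89 ± 0.48, adjusted p = 0.000195).

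The largest falls among tRNA features, internal fragments of nuclear tRNAs, rested on 1 library. They were 13 to 17 nt fragments of tRNA-Pro-CGG (log2 -3.94 ± 0.79, edgeR adjusted p = 0.00114), of tRNA-Pro-AGG and tRNA-Pro-TGG together (-3.91 ± 0.84, adjusted p = 0.00191) and of tRNA-Gly-GCC (-2.81 ± 0.62, adjusted p = 0.00251). Others were 18 to 25 nt fragments of tRNA-Gln-TTG (log2 -3.80 ± 0.79, edgeR adjusted p = 0.00156) and tRNA-Pro-TGG (-3.35 ± 0.83, adjusted p = 0.00573). Without dcl1 0 h replicate 1 these 5 log2 changes were -0.67, -0.43, -0.79, -0.61 and -0.80, and none was called, and without dcl1 0 h replicate 2 they were -4.86, -4.84, -3.62, -4.72 and -4.23. tRNA-Pro-TGG was at -2.66 without dcl1 3 h replicate 1, and without replicate 2 only 1 read was left at 3 h.

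Of the other features fixed in advance, miR158a (log2 -0.08 ± 0.35, edgeR adjusted p = 0.885), miR159 (-0.63 ± 0.37, adjusted p = 0.226) and miR166 (-0.88 ± 0.39, adjusted p = 0.0991) did not pass. Nor did miR168 (log2 -0.87 ± 0.38, edgeR adjusted p = 0.0977) and miR822 (-0.26 ± 0.42, adjusted p = 0.681), and miR398 was too low to compare (1 against 4 reads, 0.197 against 0.640 RPM, adjusted p = 0.338). The 5′ fragments of tRNA-Arg-CCT (log2 1.05 ± 0.44, edgeR adjusted p = 0.0866), tRNA-Gly-TCC (0.39 ± 0.38, adjusted p = 0.471), tRNA-Asp-GTC (-0.14 ± 0.40, adjusted p = 0.832) and tRNA-Ala-AGC (-0.38 ± 0.38, adjusted p = 0.476) did not pass either. By list, 36 of 108 snoRNAs (median 1.14, camera adjusted p = 7.07e-10), 16 of 26 snRNAs (median 1.94, adjusted p = 4.92e-07), 34 of 94 nuclear fragments of 26 to 40 nt, with 1 lower (median 0.78, adjusted p = 1.77e-06), and 12 of 30 mitochondrial tRNA features, with 2 lower (median 1.02, adjusted p = 0.00355), were higher and 10 of 47 nuclear 3′ fragments of 18 to 25 nt lower (median -0.85, adjusted p = 3.14e-07). In this order 41, 16, 38, 14 and 5 passed adjusted over the list alone, and with an estimated correlation each adjusted p was at least 0.476. Nuclear 5′ fragments of 18 to 25 nt had 3 higher and 3 lower of 42, or 4 adjusted over the list alone (median -0.41, camera adjusted p = 0.307). The lineage-specific miRNAs had a median of 0.09 and a mean of 0.21 against a downward test direction. Without dcl1 0 h replicate 1 or either dcl1 3 h library far fewer falls and somewhat fewer rises were called. Single libraries ended the calls of miR163, miR172, MIR172, MIR843, MIR390 and MIR164c. Without dcl1 0 h replicate 2 MIR164c was at log2 -1.06, and MIR843, U1.5/U1.8 and mitochondrial tRNA-Gln-TTG kept 3, 2 and 1 reads at 0 h. MIR843 was at 1.28 without dcl1 0 h replicate 1, and tRNA-Gln-TTG at 3.93 and MIR172 at 0.83 without dcl1 3 h replicate 1. MIR390 was at -2.80 without dcl1 3 h replicate 2. With DESeq2's size factors 127 features were higher and 95 lower, with library size over 18 to 28 nt reads 202 and 29, and without tRNA and rRNA reads in it 175 and 48.

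Whether wounding acted differently in dcl1 and WT was tested as an interaction (n = 2 libraries in each of 4 groups). Of 998 features 2 had a higher wounding change in dcl1 and 8 a lower one. miR843 differed by log2 3.91 ± 0.73 (edgeR adjusted p = 0.0143) and the other reads of its hairpin by 5.09 ± 0.86 (adjusted p = 0.00785). The wounding change was lower in dcl1 for internal 18 to 25 nt fragments of nuclear tRNA-Thr-TGT (log2 -3.97 ± 0.90, edgeR adjusted p = 0.0341) and tRNA-Met-CAT (-2.67 ± 0.61, adjusted p = 0.0341). It was also lower for 13 to 17 nt internal fragments of organelle tRNA-Trp (log2 -3.17 ± 0.66, edgeR adjusted p = 0.0207) and for 5′ fragments of tRNA-Leu-TAA of 13 to 17 nt (-2.94 ± 0.60, adjusted p = 0.0207) and 26 to 40 nt (-2.63 ± 0.64, adjusted p = 0.0487).

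None of the features fixed in advance passed in this interaction. miR163 (log2 1.66 ± 0.52, edgeR adjusted p = 0.105) and the 5′ fragment of tRNA-Arg-CCT (-2.10 ± 0.62, adjusted p = 0.105) had the lowest p-values. The differences of miR158a, miR159, miR166, miR168, miR390 and miR822 were log2 0.45, -0.11, 0.19, -0.07, -0.43 and -0.03 (miR398 was too low in dcl1), and those of the tRNA-Ala-AGC, tRNA-Asp-GTC and tRNA-Gly-TCC fragments 0.52, -1.36 and -1.37. Nuclear internal fragments as a list had a lower wounding change in dcl1, with 2 of 124 called, or 17 adjusted over the list alone (median -1.15, camera adjusted p = 3.37e-11). Plastid tRNA features, with 1 of 165 called, or 6 adjusted over the list alone, were lower as a list too (median -0.56, camera adjusted p = 0.000146). Called higher by camera were conserved (median 0.62, camera adjusted p = 0.00441) and lineage-specific miRNAs (median 0.49, adjusted p = 0.00296), snoRNAs (median 0.58, adjusted p = 8.03e-08) and snRNAs (median 0.65, adjusted p = 0.00319), with 1 lineage-specific miRNA past edgeR's threshold, or 2 adjusted over the list alone, and 0 members of the other 3 lists by either. With an estimated correlation the adjusted p of these 6 lists was at least 0.349. The count of 10 moved with single libraries, to 1, 6, 2 and 24 without WT 0 h replicates 1 and 2 and WT 3 h replicates 1 and 2, to 67 without dcl1 0 h replicate 2, and to 0 without dcl1 3 h replicate 1 or 2. Each named feature lost its call in at least 1 of these fits. Over them MIR843 ran from log2 3.93 to 6.67 (fitted to 3 dcl1 reads at 0 h, so no bound), miR843 from 3.01 to 4.83 and tRNA-Thr-TGT from -4.72 to -2.36, with the ends without WT 0 h replicate 1 or dcl1 0 h replicate 1 or 2. DESeq2 called 15, 3 with a higher and 12 with a lower change in dcl1, and edgeR with no low-count filter called 48.

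To find which leaf small RNAs AGO1 binds, its IP was compared with input, both times averaged (n = 6 libraries per arm). miRNAs were strongly enriched and tRNA-derived fragments strongly depleted. miR159 rose 13.7-fold (log2 3.78 ± 0.58, 175977 against 14531 RPM, edgeR adjusted p = 1.17e-07), miR158a 12.2-fold (3.61 ± 0.55, 111050.0 against 10454 RPM, adjusted p = 1.16e-07) and miR162, which targets DCL1, 24.4-fold (4.61 ± 0.62, 15762 against 935 RPM, adjusted p = 6.15e-09). The 18 to 25 nt 5′ fragments of tRNA-Arg-CCT fell 516-fold (log2 -9.01 ± 1.01, 2.54 against 1755 RPM, edgeR adjusted p = 4.71e-11). Without IP 0 h replicate 2 this change was log2 -9.93. miR390, a partner of AGO7, did not pass and its mean level was lower in the IP (log2 -1.36 ± 0.71, 123 against 411 RPM, edgeR adjusted p = 0.0708).

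Of 1363 features 180 were enriched and 958 depleted. Among 70 listed miRNAs 58 were enriched and 5 depleted, among 13 TAS features 11 were enriched and none depleted, and among 761 tRNA-derived features none was enriched and 750 were depleted. miR447 (35.3-fold, log2 5.14 ± 0.80, 452 against 20.4 RPM, edgeR adjusted p = 1.75e-07), miR398 (25.3-fold, 4.66 ± 0.74, 2512 against 122 RPM, adjusted p = 2.75e-07) and miR850 (24.1-fold, 4.59 ± 0.93, adjusted p = 1.64e-05) had the largest enrichments of listed miRNAs besides miR162, and MIR8179 hairpin reads rose 26.2-fold (11.9 against 0.608 RPM, adjusted p = 0.000601). miR166 (17.4-fold, log2 4.12 ± 0.60, edgeR adjusted p = 4.28e-08), miR163 (10.5-fold, 3.39 ± 0.67, adjusted p = 1.06e-05), miR822 (9.72-fold, 3.28 ± 0.74, adjusted p = 8.71e-05) and miR168 (6.53-fold, 2.71 ± 0.61, adjusted p = 7.41e-05) were enriched too. The passenger strand of miR168 was depleted 9.15-fold (log2 -3.19 ± 0.78, 39.6 against 406 RPM, edgeR adjusted p = 0.000219). Depleted too were hairpin reads of MIR8165 (log2 -6.15 ± 1.46, edgeR adjusted p = 0.000163), MIR852 (-4.61 ± 1.40, adjusted p = 0.00253), MIR166e (-4.25 ± 1.10, adjusted p = 0.000468) and MIR172b (-3.49 ± 1.10, adjusted p = 0.00345). MIR8179 was at log2 6.31 without input 3 h replicate 1. Without IP 3 h replicate 1 MIR852 was at -7.08 and MIR8165 kept 2 IP reads, and without IP 0 h replicate 2 MIR8165 was at -7.31.

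The 5′ fragments of tRNA-Asp-GTC (236-fold, log2 -7.88 ± 0.90, edgeR adjusted p = 6.42e-11), tRNA-Gly-TCC (106-fold, -6.72 ± 0.76, adjusted p = 6.42e-11) and tRNA-Ala-AGC (53.1-fold, -5.73 ± 0.80, adjusted p = 1.43e-08) were depleted. The most depleted tRNA features were 3′ fragments with at most 1 read over the 6 IP libraries. They came from tRNA-Ile-AAT of 18 to 25 nt (1 against 3330 reads, 0.0103 against 70.6 RPM, edgeR adjusted p = 4.75e-09), tRNA-Glu-TTC of 13 to 17 nt (1 against 1981 reads, 0.0103 against 39.1 RPM, adjusted p = 4.10e-08) and 18 to 25 nt (1 against 2102 reads, 0.0103 against 38.3 RPM, adjusted p = 1.09e-07). Another was plastid tRNA-Val of 26 to 40 nt (1 against 2088 reads, 0.00866 against 37.2 RPM, edgeR adjusted p = 1.17e-07). For tRNA-Pro-TGG of 18 to 25 nt the IP held 0 of 1333 reads, which allows up to 0.0433 RPM over the 6 libraries, against 20.2 RPM in the input (edgeR adjusted p = 2.85e-07). Of the other RNAs, snoRNA AT4G04465 fell 985-fold (log2 -9.94 ± 1.41, edgeR adjusted p = 1.88e-08), AT3G03175 175-fold (-7.45 ± 0.90, 7.60 against 1243 RPM, adjusted p = 4.03e-10) and AT1G75163 107-fold (-6.74 ± 1.44, adjusted p = 3.90e-05). Reads of AT1G09533 (3 against 1086 reads, 0.0276 against 18.8 RPM, edgeR adjusted p = 1.61e-06) and reads shared by rRNAs of the mitochondrial 26S, nuclear 25S and plastid 23S kind (log2 -6.74 ± 1.42, adjusted p = 3.17e-05) were depleted. Without IP 3 h replicate 1 the latter were at log2 -8.50 and AT4G04465 at -10.76, AT1G75163 kept 1 IP read without IP 3 h replicate 2 and AT3G03175 was at -8.18 without IP 0 h replicate 3.

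Enriched were 27 of 33 conserved miRNAs (median 2.71, camera adjusted p = 1.44e-21), 28 of 30 lineage-specific ones, with 1 depleted (median 3.53, adjusted p = 8.70e-23), 6 of 6 hormone-related ones (median 3.21, adjusted p = 6.37e-07) and 11 of 13 TAS features (median 2.56, adjusted p = 3.62e-09), or 27, 29, 6 and 11 adjusted over the list alone. Nutrient-responsive (8 of 9), phased-siRNA-trigger (5 of 7) and pathway-targeting miRNAs (3 of 3) were called enriched, with medians of 2.93 to 3.99. Called depleted were rRNAs (16 of 16) and all 6 sets of tRNA fragments, such as nuclear 3′ (49 of 49) and internal ones (158 of 166), with medians of -7.95 to -4.89. The 14 called lists had camera adjusted p at most 0.0258, and adjusted p at least 0.109 with an estimated correlation. Adjusted over the list alone, 159 internal fragments passed and the other counts were the same. Medians and test direction differed in sign for passenger strands (median -1.97, direction up, camera adjusted p = 0.0993), miRNAs that start with A (-0.92, up, 0.0706), snoRNAs (-3.28, up, 0.205) and snRNAs (-1.79, up, 0.0620).

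By share of reads, miRNAs were 63.14% of the IP and 6.175% of the input, 12-fold higher, and tRNA-derived reads 0.1778% and 25.32%, 131-fold lower, beyond the input mean in 6 of 6 libraries (exact permutation p = 0.005 each, the smallest possible, adjusted p = 0.005). Reads of 18 to 25 nt began with U in 91.83% of IP reads and 30.56% of input reads (exact permutation p = 0.005, adjusted p = 0.005). The split of calls moved with the scaling, to 268 enriched and 722 depleted with TMM factors and to 81 and 1029 with DESeq2's size factors, but neither reversed the median of the miRNAs (log2 5.32 and 1.39).

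The AGO1 IP was also compared with the mock IP (n = 6 libraries per arm). Relative to it 50 of 70 listed miRNAs and 7 of 13 TAS features were enriched, and 559 of 761 tRNA-derived, 16 of 16 rRNA and 177 of 216 snoRNA features were depleted. miR158a was 4.49-fold higher (log2 2.17 ± 0.52, 111050.0 against 30643 RPM, edgeR adjusted p = 0.000372), miR163 6.1-fold (2.61 ± 0.64, adjusted p = 0.000499) and miR166 4.16-fold (2.06 ± 0.55, adjusted p = 0.00112). The tRNA-Arg-CCT 5′ fragment was 42-fold lower (log2 -5.39 ± 0.89, 2.54 against 82.4 RPM, edgeR adjusted p = 2.71e-06). It was at log2 -6.31 without IP 0 h replicate 2 and -4.66 without mock 0 h replicate 3, and miR163 at 3.27 without mock 3 h replicate 2.

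In all, 200 features were enriched and 763 depleted. miR168 (4.13-fold, log2 2.05 ± 0.59, edgeR adjusted p = 0.00218), miR159 (3.26-fold, 1.71 ± 0.53, adjusted p = 0.00417) and miR398 (3.06-fold, 1.61 ± 0.65, adjusted p = 0.0249) were enriched. miR822 (log2 1.26 ± 0.69, edgeR adjusted p = 0.0980) and miR390 (-0.09 ± 0.70, adjusted p = 1.00) did not pass. Hairpin reads rose for MIR5640 (66.6-fold, log2 6.06 ± 1.35, edgeR adjusted p = 0.000158), MIR5997 (44.6-fold, 5.48 ± 1.5, adjusted p = 0.00140) and MIR8179 (33.3-fold, 5.06 ± 1.46, adjusted p = 0.00216). MIR8179 was at log2 7.05 without mock 0 h replicate 3 and 4.35 without mock 0 h replicate 2, and MIR5997 at 6.08 without mock 3 h replicate 2. tasiRNA reads shared by TAS1A and TAS1B (234 against 2 reads, 11.5 against 0.0264 RPM, edgeR adjusted p = 7.03e-05) and MIR5645f hairpin reads (578 against 3 reads, 10.7 against 0.355 RPM, adjusted p = 0.000115) had at most 3 reads in the mock. The 5′ fragments of tRNA-Asp-GTC (31.4-fold, log2 -4.97 ± 0.80, edgeR adjusted p = 2.00e-06), tRNA-Ala-AGC (19.6-fold, -4.29 ± 0.75, adjusted p = 6.89e-06) and tRNA-Gly-TCC (13-fold, -3.70 ± 0.67, adjusted p = 1.24e-05) were lower.

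Among the largest depletions were 26 to 40 nt 5′ fragments of mitochondrial tRNA-Glu-TTC (209-fold, log2 -7.71 ± 1.32, edgeR adjusted p = 5.08e-06) and 13 to 17 nt 5′ fragments of nuclear tRNA-Thr-TGT (181-fold, -7.50 ± 1.30, adjusted p = 5.59e-06). Fragments from 3′ ends were nearly absent from the IP for the tRNA-Pro isoacceptors together (1 against 568 reads, 0.0103 against 16.0 RPM, edgeR adjusted p = 1.19e-05) and plastid tRNA-Gln (1 against 484 reads, 0.0103 against 18.7 RPM, adjusted p = 2.35e-06). For mitochondrial tRNA-His-GTG of 26 to 40 nt the IP held 0 reads, which allows up to 0.0433 RPM over the 6 libraries, against 332 reads and 11.1 RPM in the mock (edgeR adjusted p = 0.000107). Of the snoRNAs, AT1G75166 fell 393-fold (log2 -8.62 ± 1.44, edgeR adjusted p = 3.54e-06), reads shared by AT1G04527, AT1G06667 and AT1G06673 345-fold (-8.43 ± 1.56, adjusted p = 1.63e-05) and reads shared by AT3G47342 and AT5G08860 252-fold (-7.98 ± 1.55, adjusted p = 3.21e-05). AT2G09465 (3 against 668 reads, 0.0314 against 22.7 RPM, edgeR adjusted p = 1.30e-05) and U60.2F (3 against 645 reads, 0.0311 against 23.8 RPM, adjusted p = 3.54e-06) were nearly absent from the IP. Without IP 3 h replicate 1 tRNA-Thr-TGT was at log2 -8.95 and AT3G47342 kept 0 IP reads (log2 -7.06 without mock 0 h replicate 1). AT1G75166 kept 1 IP read without IP 3 h replicate 2 and AT1G04527 0 without IP 0 h replicate 2.

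Enriched were 25 of 33 conserved (median 1.97, camera adjusted p = 1.62e-14) and 21 of 30 lineage-specific miRNAs (median 2.02, adjusted p = 2.01e-14), or 26 and 21 adjusted over the list alone. Called enriched too were passenger strands (3 of 6), nutrient-responsive (4 of 9), hormone-related (6 of 6), phased-siRNA-trigger (6 of 7), pathway-targeting (3 of 3) and A-starting miRNAs (2 of 6) and TAS features (7 of 13), with medians of 1.07 to 2.05. Nuclear 5′ fragments of 18 to 25 nt (36 of 44) and internal fragments (127 of 166), plastid tRNA features (152 of 173), snoRNAs (177 of 216), rRNAs (16 of 16) and plastid rRNAs (10 of 10) were called depleted, with medians of -4.84 to -4.00. These lists had camera adjusted p at most 0.00402 and, with the first 2, adjusted p at least 0.169 with an estimated correlation. Adjusted over the list alone, 153 plastid features passed and the other counts were the same. The snRNA list was called up although its median was below 0 (median -0.64, camera adjusted p = 0.0222, adjusted p = 0.390 with estimated correlation), and mitochondrial tRNA features had a median of -2.85 with an upward test direction (camera adjusted p = 0.845). As a share of reads, miRNAs were 63.14% of the AGO1 IP and 17.92% of the mock, above the mock mean in 6 of 6 libraries (exact permutation p = 0.015, adjusted p = 0.0159). Mock libraries differed from each other, with miRNA shares from 2.02% to 40.2%. In 6 of 6 the miRNA composition was nearer to the AGO1 IP than to the input. The call of miR398 was lost when any of 6 libraries was left out (log2 1.30 to 2.61 over all), and those of the tRNA-Pro and mitochondrial tRNA-His 3′ fragments were lost without mock IP 0 h replicate 2 and mock IP 3 h replicate 1. TMM factors gave 308 enriched and 587 depleted features and DESeq2's size factors 63 and 885.

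In the input libraries total small RNA of the tagged plants was compared between times (n = 3 libraries per time point). Of 173 plastid tRNA features 17 rose. The 13 to 17 nt 5′ fragments of plastid tRNA-Pro rose 55.5-fold (log2 5.79 ± 1.02, 10518 against 189.6 RPM, edgeR adjusted p = 0.000250) and the 18 to 25 nt 5′ fragments of plastid tRNA-Arg 70.5-fold (6.14 ± 1.27, 2178 against 30.8 RPM, adjusted p = 0.00121). The 18 to 25 nt internal fragments of organelle tRNA-Met rose 144-fold (log2 7.17 ± 1.70, edgeR adjusted p = 0.00713). Those of plastid tRNA-Phe rose 58-fold (log2 5.86 ± 1.31, edgeR adjusted p = 0.00358) and 26 to 40 nt internal fragments of plastid tRNA-Pro 129-fold (7.01 ± 1.59, adjusted p = 0.00433).

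With the spread shared over all 18 libraries, 44 features were higher and none lower, of which 43 were tRNA-derived. No feature fixed in advance passed. The closest was the tRNA-Arg-CCT 5′ fragment (log2 3.37 ± 1.07, edgeR adjusted p = 0.0602). The log2 changes of miR158a, miR159, miR163, miR166, miR168, miR390, miR398 and miR822 were -1.60, -1.55, -1.78, -2.10, -1.88, -2.25, -2.03 and -1.44, and those of the tRNA-Ala-AGC, tRNA-Asp-GTC and tRNA-Gly-TCC fragments -1.36, 1.30 and 2.05. The median of the listed miRNAs was log2 -1.84, but -0.29 with DESeq2's size factors, -1.14 without tRNA and rRNA reads in library size and -2.57 with TMM, with 0, 0, 0 and 8 of them lower. In a fit of the 6 input libraries alone, on total reads, chosen after seeing the data, 412 of 1330 features were higher and 357 lower. There 55 of 62 listed miRNAs, 164 of 209 hairpin features and 10 of 11 TAS features fell and none rose.

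As a list, none of 33 conserved miRNAs passed, but 4 did when adjusted over the list alone (median -2.01, camera adjusted p = 2.08e-07). Higher were 7 of 166 nuclear internal fragments (median 1.85, camera adjusted p = 1.87e-13) and 17 of 173 plastid tRNA features (median 1.39, adjusted p = 7.68e-07), or 16 and 26 adjusted over the list alone. Lineage-specific, passenger-strand, nutrient-responsive, hormone-related, phased-siRNA-trigger and pathway-targeting miRNAs, TAS features and nuclear 3′ fragments of 18 to 25 nt were called lower with 0 members past edgeR's threshold (medians -2.47 to -1.17), or 0, 0, 2, 1, 0, 3, 0 and 0 adjusted over the list alone. Nuclear fragments of 26 to 40 nt (6 of 121, median 1.00) and snRNAs (1 of 51, median 1.66) were called higher, or 7 and 1 adjusted over the list alone. The 13 called lists had camera adjusted p at most 0.0287, and adjusted p at least 0.336 with an estimated correlation. Nuclear 5′ fragments of 18 to 25 nt had 3 of 44 higher, with a median of -0.28, a mean of 0.30 and a downward test direction (camera adjusted p = 0.974). The rRNA list had a median of 0.34 and a mean of 0.11 with a downward direction (camera adjusted p = 0.787). DESeq2 called 223 features, and TMM factors gave 23 higher and 11 lower. The count was 175 without the 4 libraries with the fewest genome matches, with 30 listed miRNAs lower, 0 without the 6 libraries of under 2000000 reads, 9, 13 and 10 without input 0 h replicates 1, 2 and 3, and 95 and 69 without mock IP 0 h replicates 1 and 2. The calls of the named internal fragments were lost in some of these fits, and plastid tRNA-Pro of 26 to 40 nt was at log2 6.32 without input 3 h replicate 1.

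Within the AGO1 IP no wounding change passed (n = 3 libraries per time point). edgeR called 0 of 1363 features, with 84 at an unadjusted p under 0.05, and DESeq2 called 15 (14 higher and 1 lower). The log2 changes were 0.35 ± 0.71 for miR158a, -0.47 ± 0.73 for miR159, -0.76 ± 0.76 for miR166 and -2.51 ± 1.20 for the tRNA-Arg-CCT 5′ fragment. Those of miR163, miR168, miR390, miR398 and miR822 were -0.37, -0.69, -0.34, -0.68 and -0.93, and those of the tRNA-Ala-AGC, tRNA-Asp-GTC and tRNA-Gly-TCC fragments 1.03, -0.80 and 0.51. For each of these 12 features edgeR's adjusted p was at least 0.789.

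Camera called 5 lists, with 0 members past edgeR's threshold. Conserved (median -0.65, camera adjusted p = 0.00940), lineage-specific (median -0.43, adjusted p = 0.0385) and nutrient-responsive miRNAs (median -1.01, adjusted p = 0.00940) were lower, and snoRNAs (median 0.50, adjusted p = 0.00940) and nuclear tRNA fragments of 26 to 40 nt (median 0.00, adjusted p = 0.00940, mean 0.51) higher. With an estimated correlation each adjusted p was 0.681. Adjusted over the list alone, 3 of the 26 to 40 nt fragments and 0 members of the other lists passed. The median of all listed miRNAs was -0.56, but 0.15 with DESeq2's size factors. The plastid rRNA list had a median of 0.01 with a downward test direction (camera adjusted p = 0.283). Simulated changes of 2-fold and 4-fold were recovered in 0 of 100 features each in this design, so changes of that size were not detectable at this depth and spread.

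Whether the IP to input ratio differed after wounding was tested as an interaction (n = 3 libraries in each of 4 groups). With the spread shared over 18 libraries, this ratio was lower after wounding for 7 features, all tRNA-derived, and higher for none. Fits chosen after seeing the data gave more calls. The 12 input and IP libraries alone gave 66, with 5 listed miRNAs, 16 tRNA-derived and 5 snRNA and snoRNA features higher and 35 and 4 of the last 2 classes lower. Without the 4 libraries with the fewest genome matches 9 were higher, 7 of them listed miRNAs, and 12 tRNA-derived ones lower. The leading ones were the 18 to 25 nt 5′ fragments of tRNA-Arg-ACG (log2 -8.83 ± 1.62, edgeR adjusted p = 0.000897) and the 13 to 17 nt 5′ fragments of plastid tRNA-Pro (-7.08 ± 1.32, adjusted p = 0.000897). At 3 h all 18 IP reads of the tRNA-Arg-ACG fragment lay in replicate 1. Without that library 0 reads were left, and it was at log2 -7.91 without IP 3 h replicate 2 and -8.24 without IP 0 h replicate 2, which moved plastid tRNA-Pro to -4.90. The 13 to 17 nt 5′ fragments of tRNA-Ala-AGC differed by log2 -5.93 ± 1.21 (edgeR adjusted p = 0.00311). In the input these were at 506.6 ± 98.9 and 20040 ± 2165 RPM at 0 h and 3 h (SD), and in the IP at 34.1 and 25.5. Also lower were 13 to 17 nt 5′ fragments shared by tRNA-Ala-CGC and tRNA-Ala-TGC (log2 -5.68 ± 1.32, edgeR adjusted p = 0.0119) and 13 to 17 nt internal fragments of tRNA-Ser-AGA (-6.57 ± 1.51, adjusted p = 0.0119).

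No feature fixed in advance passed in this interaction, and the lowest p-value was that of the tRNA-Arg-CCT fragment (log2 -5.87 ± 1.61, edgeR adjusted p = 0.0827). The differences for miR158a, miR159, miR163, miR166, miR168, miR390, miR398 and miR822 were log2 1.95, 1.09, 1.41, 1.34, 1.19, 1.91, 1.36 and 0.50, and for the tRNA-Ala-AGC, tRNA-Asp-GTC and tRNA-Gly-TCC fragments 2.39, -2.11 and -1.53. By list, conserved and lineage-specific miRNAs, TAS features and nuclear 3′ fragments of 18 to 25 nt were called higher with 0 members past either adjustment (medians 1.34 to 1.77). Nuclear internal fragments (1 of 166 called), those of 26 to 40 nt (0), plastid tRNA features (1 of 173) and snRNAs (0) were called lower (medians -1.85 to -0.65), or 1, 0, 2 and 0 adjusted over the list alone. Camera adjusted p was at most 0.0228 for these 8 lists, and each adjusted p was 0.590 with an estimated correlation. Without single libraries the count was 3 (input 0 h replicate 1), 3 (input 0 h replicate 3), 2 (AGO1 IP 0 h replicate 2), 20 (AGO1 IP 3 h replicate 1), 4 (AGO1 IP 3 h replicate 2) and 17 (mock IP 0 h replicate 1). Calls of the plastid tRNA-Pro, tRNA-Ser-AGA and tRNA-Ala-CGC/TGC fragments were lost in some. tRNA-Ser-AGA was at log2 -7.96 without IP 3 h replicate 1 and -5.52 without IP 0 h replicate 2, and without IP 3 h replicate 3 tRNA-Ala-CGC/TGC was at -7.02 and tRNA-Ala-AGC of 13 to 17 nt at -6.56. DESeq2 called 38, 6 higher and 32 lower, TMM factors gave 1 higher and 4 lower, library size over 18 to 28 nt reads gave 19, and without the 6 libraries of under 2000000 reads the count was 0. Of 100 splits drawn, 6 called 7 or more.

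**Figure D3:**
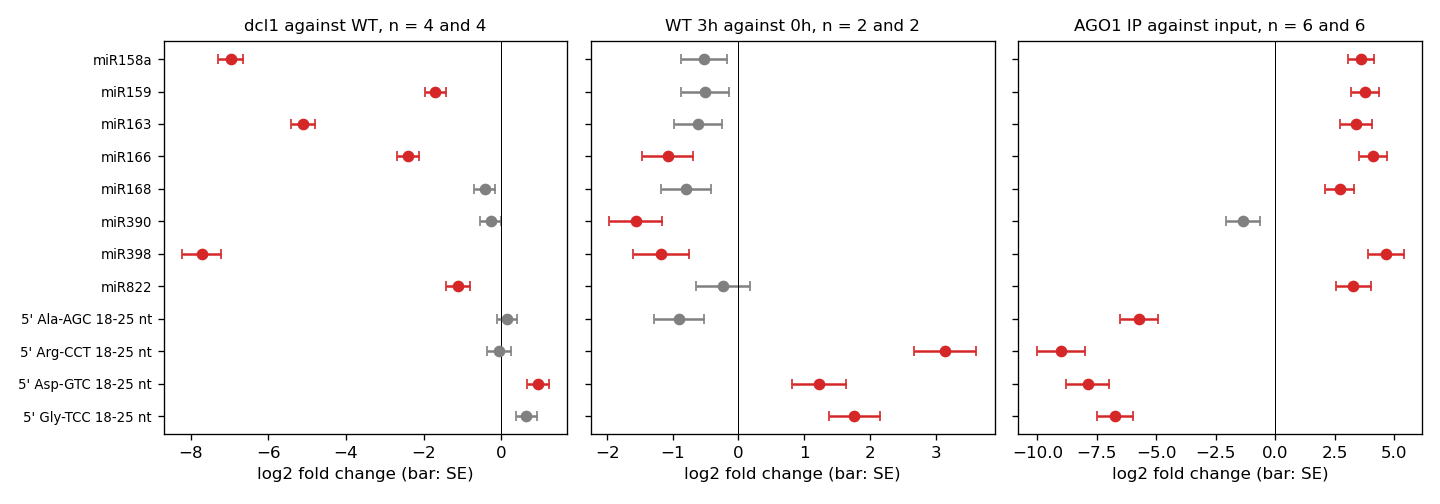
Log2 fold changes (points) with SE (bars) of the 12 features fixed in advance, in dcl1 against WT (n = 4 and 4), in WT 3 h after wounding against 0 h (n = 2 and 2) and in the AGO1 IP against input (n = 6 and 6). Red points passed the adjusted threshold and grey points did not, with miR158a at -6.97 in dcl1 and miR159 at 3.78 in the IP.

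Positions are in TAIR10.1 coordinates. The mature miR158a (TCCCAAATGTAGACAAAGCA) lies on chromosome 3, 3366349 to 3366368, and miR159 (TTTGGATTGAAGGGAGCTCTA) on chromosome 1, 27713234 to 27713254, both on the - strand outside protein-coding genes. miR163 (TTGAAGAGGACTTGGAACTTCGAT) lies on chromosome 1, 24884359 to 24884382, and miR173 (TTCGCTTGCAGAGAGAAATCAC) on chromosome 3, 8236161 to 8236182, both outside protein-coding genes. miR398 (TGTGTTCTCAGGTCACCCCTG, made from 2 genes) lies at 4691107 to 4691127 of chromosome 5 in a UTR exon of AT5G14550 on the other strand. miR822 (TGCGGGAAGCATTTGCACATG) lies on chromosome 5, 897287 to 897307, in an intron of AT5G03553 on the other strand. miR166 (TCGGACCAGGCTTCATTCCCC) is made from 7 genes, with a copy on chromosome 2, 19176241 to 19176261. miR168 (TCGCTTGGTGCAGGTCGGGAA, chromosome 4, 10578652 to 10578672) and miR390 (AAGCTCAGGAGGGATAGCGCC, chromosome 2, 16061971 to 16061991) are made from 2 genes each. miR843 (TTTAGGTCGAGCTTCATTGGA) lies on chromosome 3 at 17742147 to 17742167.

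As tRNA features pool sequences, the most abundant is given for some named ones with its share of the feature's reads and, where the genome holds it, the position of 1 gene copy. The 18 to 25 nt 5′ fragments fixed in advance were led by GGGGATGTAGCTCAGATGGT (32.9%, chromosome 1, 2025356 to 2025375) for tRNA-Ala-AGC and GCGCCTGTAGCTCAGTGGA (71.5%, chromosome 1, 18387802 to 18387820) for tRNA-Arg-CCT. For tRNA-Asp-GTC this was GTCGTTGTAGTATAGTGGT (29.3%, chromosome 1, 877648 to 877666), and for tRNA-Gly-TCC GCGTCTGTAGTCCAACGGT (50.6%, chromosome 1, 2588525 to 2588543). Those of tRNA-Arg-ACG were led by GACTCTGTGGCCCAATGGA (73.4%, chromosome 2, 10373576 to 10373594), in a UTR exon of AT2G24390. The other tRNA positions given overlap no protein-coding gene. Plastid tRNA-Arg fragments were led by GGGCTTGTAGCTCAGAGGA (96.6%, plastid genome, 130329 to 130347) at 18 to 25 nt. Plastid tRNA-Pro gave AGGGATGTAGCGCAGCT (84.4%, plastid genome, 66547 to 66563) from its 5′ end.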

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

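The tests of RNA breakdown, of cleavage along the tRNA, of reads of 13 to 17 nt, of tRNA reads against others of the same length, of dilution and of unmatched mock reads, and the fits of the input libraries alone and without libraries under 2000000 reads, were chosen after the results were seen.

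The wounding change differed between dcl1 and WT for 10 features by the interaction test. The difference was log2 5.09 ± 0.86 for other reads of the MIR843 hairpin (edgeR adjusted p = 0.00785) and 3.91 ± 0.73 for miR843 (adjusted p = 0.0143). For 5′ fragments it was, at 13 to 17 nt, -2.17 ± 0.50 for tRNA-Ala-AGC, -2.47 ± 0.52 for tRNA-Ala-CGC and -2.94 ± 0.60 for tRNA-Leu-TAA. It was -2.63 ± 0.64 for tRNA-Leu-TAA of 26 to 40 nt and -2.51 ± 0.58 for plastid tRNA-Lys of 18 to 25 nt. For internal fragments it was -2.67 ± 0.61 for tRNA-Met-CAT and -3.97 ± 0.90 for tRNA-Thr-TGT of 18 to 25 nt and -3.17 ± 0.66 for organelle tRNA-Trp of 13 to 17 nt. Their edgeR adjusted p-values lay between 0.0207 and 0.0487. The tRNA-Ala-AGC, tRNA-Ala-CGC and plastid tRNA-Lys fragments fall outside the naming rule.

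The IP to input ratio differed after wounding for 7 tRNA features, none enriched. The difference was log2 -8.83 ± 1.62 for 5′ fragments of tRNA-Arg-ACG of 18 to 25 nt and, for 5′ fragments of 13 to 17 nt, -7.08 ± 1.32 for plastid tRNA-Pro, -5.93 ± 1.21 for tRNA-Ala-AGC, -5.68 ± 1.32 for tRNA-Ala-CGC and tRNA-Ala-TGC together, -5.59 ± 1.30 for organelle tRNA-Asp and -5.40 ± 1.24 for tRNA-Ala-CGC. Internal tRNA-Ser-AGA fragments of 13 to 17 nt differed by -6.57 ± 1.51. edgeR adjusted p-values lay between 0.000897 and 0.0119. The organelle tRNA-Asp and the tRNA-Ala-CGC fragments fall outside the naming rule. The other 5 rose by log2 5.3 to 5.8 in the input alone, so a change of AGO1 binding is not shown. Other splits gave as large a count, as 6 of 100 drawn, the real one included, called 7 or more features. The highest, 110, exchanged AGO1 IP replicate 1 between times and points to an untested structure of the samples.

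The first pattern is the rise of the tRNA-derived share after wounding, 3.67-fold in WT, 1.88-fold in dcl1 and 3.63-fold in the input. General RNA breakdown would raise rRNA fragments too. Their share changed by a factor of 0.812 (geometric mean over the 3 sample types), and the miRNA share by 0.463. Such shares are diluted by the tRNA-derived reads, so they cannot tell whether rRNA fragments rose in amount. The snRNA and snoRNA share changed by 0.909 in WT, 1.56 in dcl1 and 0.681 in the input. Of their features 33 and 52 were higher in WT and dcl1. Breakdown thus stays open, whether general or sparing rRNA. Cleavage at random along the tRNA would raise both ends alike, but 5′ fragments of nuclear tRNAs changed at least 2.65 times as much as 3′ fragments in each sample type. Size selection would change other reads of the same length alike. These changed by 0.851 at 13 to 17 nt and 1.31 at 26 to 40 nt (WT 1.47, dcl1 1.46, input 1.04). The tRNA-derived share changed 2.62 (WT), 1.55 (dcl1) and 3.38 (input) times as much as other reads of each length would give. Without any 1 library this stayed at least 1.5. Size selection may thus add a part, but as the whole cause it is argued against, least clearly in dcl1. Cleavage of tRNAs induced by wounding stays open, as does a change with time, and neither was tested directly.

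The second pattern is the lower miRNA level in wounded WT (median log2 -0.80). Dilution by the larger tRNA-derived fraction may contribute, since the median was -0.42 with library size over all but tRNA- and rRNA-derived reads. As that value lies between no change and the full change, dilution and a change of miRNAs cannot be told apart.

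The third pattern is the small count of 44 wounding calls in the input. Spread shared with the IP and mock libraries is a candidate cause, since the 6 input libraries alone gave 769 calls with a coefficient of variation of 0.388 instead of 0.953. Leaving out the 6 libraries under 2000000 reads gave 0 calls. That leaves 2 input libraries per time, and with 3 no simulated 4-fold change was recovered, so an effect of the shallow replicate 3 libraries stays open.

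Mock IP libraries differed in miRNA share, up to 7.61-fold over genome-matched reads.

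For the other comparisons of at least 3 libraries per arm, relabelled splits were counted. For AGO1 IP against input, 1 of 100 splits drawn, the real one with 1138 calls, reached that count and the highest other gave 644. For IP against mock this was 1 of 100 with 963 and 664, so chance is unlikely for both. For dcl1 against WT there are 18 splits, too few for a share under 0.05, with 286 calls in the real one (1 as large) and 10 in the highest other. In the input there are 10 splits, also too few, with 44 calls (1 as large) and 0 in the highest other, and in the AGO1 IP 10 of 10 splits reached the real count of 0, with 10 in the highest other.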

How the results depend on the processing

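Over 4833 values of named features under all alternatives, 4474 kept their direction and side of the threshold, 219 kept direction but lost the call, 76 gained it and 64 reversed, none of them a called feature. The causes were not tested except where fewer libraries or another scaling defines the alternative. Many refits left out a library of neither arm or altered no count of the feature, so the 4474 overstates stability. Against the total read count, the median of all features shifted by 0.44 (18 to 28 nt), 0.34 (no tRNA or rRNA) and -0.25 (TMM) for dcl1, by 0.55, 0.37 and, with DESeq2, -0.27 for wounding in WT, by 2.22 (TMM) and -1.81 (DESeq2) for IP against input and by 1.5 and -1.74 for IP against mock. With DESeq2 it shifted by -0.12 for wounding in dcl1, 0.14 for its interaction, 0.72 for wounding in the IP, 1.57 in the input and -0.77 for their interaction, with 18 to 28 nt reads by 0.28, -0.27, 0.04, 0.68 and -0.63, and with TMM by 0.25, -0.69 and 0.96 for the last 3. Of 157 calls of named features, 60 moved by over 1.5-fold when some library was left out.

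Counts of features that moved over 1.5-fold were 48 for the wounding by dcl1 interaction with no low-count filter. With DESeq2 they were 15 for wounding in the IP, 223 in the input and 38 for the wounding by AGO1 interaction. For the input and that interaction they were 109 and 19 with library size over 18 to 28 nt reads, 94 and 17 without tRNA and rRNA reads, 175 and 21 without the 4 libraries with the fewest genome matches, and 0 and 0 without the 6 shallow libraries. The 6 input libraries alone gave 769 and the 12 input and IP libraries alone 66 for the interaction. With an estimated correlation, 1 list was called for dcl1 against WT and 0 in each of the other 8 comparisons. With input libraries as a further stratum, 18 of 21 class shares passed for wounding, with log2 -1.11 for miRNAs and 1.55 for tRNA-derived reads (exact permutation p = 0.00278, the smallest possible).

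The replicate numbers were not taken to pair the samples, since not every correlation of deviations was over 0.1. Those of same-numbered libraries were -0.247 to 0.199 in total RNA (4 of 12 over 0.1). With 2 libraries per group, other numbers give these values with the sign changed and so offer no comparison. In the IP set they were -0.095 to 0.345 for same-numbered libraries (10 of 45, against 3 of 90 for other numbers, a hint of shared deviations). With the replicate block the counts were 282, 286, 243, 8, 1138, 953, 0, 58 and 10 in the order dcl1, wounding in WT, in dcl1 and their interaction, IP against input, IP against mock, wounding in IP, in input and their interaction, and the miRNA share of IP against mock (log2 2.52) no longer passed.

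Reversed values, none called, are in log2. With DESeq2 they were miR159 0.05, miR168 0.08 and miR822 0.12 (interaction with dcl1), miR159 0.17, miR163 0.16, miR390 0.48 and miR398 0.24 (wounding in IP), miR159 0.04, miR822 0.06 and tRNA-Ala-AGC 0.20 (input), and miR822 -0.15 (interaction with AGO1). With TMM they were tRNA-Ala-AGC -0.10 (dcl1) and miR390 0.77 (IP against input) and 1.54 (IP against mock). Library size over 18 to 28 nt reads gave miR168 0.01, miR390 0.20 and tRNA-Arg-CCT 0.36 (dcl1), miR158a 0.03, miR159 0.06 and miR822 0.33 (wounding in WT), miR158a 0.24, miR822 0.02 and tRNA-Asp-GTC 0.19 (wounding in dcl1) and miR166 -0.07 (interaction with dcl1). Leaving tRNA and rRNA out of library size gave miR390 0.10 and tRNA-Arg-CCT 0.26 (dcl1), miR822 0.15 (wounding in WT), miR158a 0.07 and tRNA-Asp-GTC 0.01 (wounding in dcl1), miR166 -0.04 and miR822 -0.19 (interactions with dcl1 and AGO1). Exact mature counts gave miR398 2.40 and 3.54 (wounding in dcl1 and the interaction, fitted to 1 dcl1 read and no measure of change) and miR822 0.02 (interaction with dcl1). For miR390 in IP against mock the block gave 0.50 and leaving out shallow libraries 0.76, which also gave miR159 0.01 (wounding in IP).

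Leaving out each library in turn gave counts of 179 to 346 (wounding in WT), 97 to 260 (in dcl1), 0 to 67 (interaction with dcl1), 9 to 95 (input) and 2 to 20 (interaction with AGO1), with called lists of 7 to 13, 4 to 9 and 5 to 11 for the first 3 and 2 to 8 for wounding in the IP. The log2 values that crossed 0 ran from -0.35 to 0.44 for tRNA-Arg-CCT (dcl1), -0.92 to 0.05 for miR159 and -0.58 to 0.24 for miR822 (wounding in WT), -0.31 to 0.20 for miR158a, -0.64 to 0.03 for miR822 and -0.42 to 0.22 for tRNA-Asp-GTC (wounding in dcl1). In the interaction with dcl1 they ran from -0.67 to 0.29 for miR159, -0.15 to 0.64 for miR166, -0.48 to 0.24 for miR168, -3.02 to 0.50 for miR398 (fitted to at most 5 dcl1 reads) and -0.50 to 0.32 for miR822. They ran from -0.38 to 0.60 for miR390 (IP against mock) and -1.44 to 0.07 for tRNA-Asp-GTC (wounding in IP). Where 1 library was left in an arm, it was assumed to vary like the other groups.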

Other observations

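Reads of 24 nt took 24.82% of unwounded and 16.46% of wounded WT libraries (n = 2 each) and 20.85% and 7.178% of the input libraries (n = 3 each). In the AGO1 IP tasiRNAs of TAS2 were at 33510 RPM at 0 h and 27610 at 3 h. In total RNA they were at 8655 and 4345 in WT and 11.2 and 12.6 in dcl1. Reads of 24 nt took 4.529% of the AGO1 IP and 4.694% of the mock IP (exact permutation p = 0.960, n = 6 libraries each).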
